A study of Mus musculus with 8 samples.

How the data were processed

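RNA sequencing was used to measure gene expression in natural killer (NK) cells sorted from BALB/c mice that carried a subcutaneous tumour of CT26 cells without β2-microglobulin. The labels describe tissue digestion with collagenase, dispase, hyaluronidase and DNase at 37 °C for 60 minutes, lysis of red cells, a Percoll step for tumours, and magnetic and flow sorting, without naming the markers used for the sort. Libraries were made from 20 ng of RNA with an integrity score above 7, by a directional method with selection of polyadenylated RNA, and were sequenced as pairs of 60 nt reads. Samples were grouped by their titles into 4 spNK and 4 tuNK libraries. The tissue tag and the source name contradict the title in all 8 samples, since the 4 samples titled spNK are tagged as tumour and the 4 titled tuNK as spleen. Both readings put the same samples together, so the tests do not depend on the choice, and only the naming of the direction does. No sample was assigned from its values.

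Per the submitters' notes, reads were checked with FastQC 0.11.9, aligned with STAR and quantified with Salmon against GRCm38 (mm10). The versions of STAR and Salmon, the annotation release and the strand setting are not given in the sources used here. The deposited gene table holds estimated counts (expected counts, not normalised), of which 7.9 to 8.82% per library were not whole numbers. A second deposited table holds TPM (length-scaled abundances), and each library summed to 1000000. Both tables list 45706 genes in 8 libraries, and 0 columns of sample values were left without a sample. Gene positions are those of GENCODE M21, which holds 45143 of the gene identifiers.

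Estimated counts were rounded to whole numbers. Library totals ran from 38745733 to 53886933. Genes were kept with the filterByExpr rule of edgeR by group, which left 14006 genes for testing. Libraries were scaled with TMM, and groups were compared with the edgeR quasi-likelihood F test with robust settings and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Log2 fold changes are tuNK minus spNK with their standard errors. Levels of single genes are TMM-scaled counts per 1000000 (CPM), given as mean ± SD of 4 libraries. Sums and log2 differences of marker lists leave out the TMM factors (1.046 to 1.072 in spNK, 0.916 to 0.998 in tuNK). Only their leukocyte-scaled values include these factors. The common dispersion was 0.071, a coefficient of variation of 0.266 between libraries of a group. Where all libraries of a group had 0 counts, the fold was computed against a floor of 3 counts per library, a mean of 0.0631 CPM in spNK and 0.0751 CPM in tuNK, and is given as a lower bound. Such floors cover counting error only, since PCR copies are not independent molecules.

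The gene lists, the tests and the rule for naming genes were fixed before the data were examined. There were 27 program lists, 14 lists of cell type markers and 1 list of mitochondrially encoded transcripts. Of 809 list entries, 792 matched the symbols of the tables, 4 matched through the reference annotation, and 13 were left out. Program lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 27 lists. Camera was repeated with a correlation estimated from the data, and fry was run beside it. The fry test asks whether the genes of a list move one way on balance and does not compare them with other genes. Marker lists were compared as the log2 of their summed CPM plus 1, with a two-sided exact permutation test over the 70 assignments of the libraries, adjusted over 15 lists. The smallest p that test allows is 0.0286.

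Genes were named by a rule with 3 parts. A panel of 40 genes was named whatever its result, and the results of a few genes that met the rule are not reported here. The 10 genes with the largest rise and the 10 with the largest fall were named among those past the threshold with a mean of at least 10 CPM in the higher group and no overlap between groups. That part left out predicted genes, pseudogenes, antigen receptor segments and members of the marker lists, which are described with their lists. For each program list, up to 4 members with the smallest adjusted p were eligible. In all 161 genes met the rule, and 6571 met the conditions of its second part before ranking. Other genes named in the text were chosen after their values were seen and are marked as such, apart from marker genes.

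Alternatives fixed before the data were examined were scaling with the DESeq2 size factors, with the upper quartile or by library size alone; no filter or a filter of at least 1 CPM in 4 libraries; DESeq2, limma-voom, and limma-trend on log2 TPM with an offset of 1 or 0.1; offsets for transcript length; the replicate number as a block; a test against a fold of 1.5; and leaving out each library in turn. An alternative chosen after mesenchymal genes had been seen in tuNK scaled each library to 32 genes expressed across leukocytes. The list of 32 genes was written before their values were looked at, and it holds Itgb2, Itgal and Il2rg, which also belong to program lists. Leaving out spNK 3 and tuNK 1 together was also chosen after seeing the data, since spNK 3 held the most B cell, plasma cell and erythroid markers of its group and tuNK 1 the most mesenchymal markers. In each group of 4 libraries, values of the named genes with a mean of at least 1 CPM and of the marker lists were screened for a single distant library with Dixon's ratio, the gap to the nearest library divided by the range, against its 95% critical value.

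The steps were tested on simulated data in which 200 of 14006 genes were changed. The edgeR step recovered 36% of genes changed by a fold of 1.5, 62% at a fold of 2, 92% at 4 and 96% at 8, with 13 false calls among 156. The simulated changes were few and balanced between higher and lower. These rates therefore do not carry over to the real comparison, in which 69.6% of genes were called. Camera ranked a changed list at 1 and called 2 lists where only 1 was changed. Scaling to the leukocyte genes returned a median log2 fold change of -0.019 for genes whose only simulated change was dilution. The leukocyte genes were diluted there by the same factor, so the simulation does not test whether they keep their level within the real cells. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.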

Results

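Gene expression was compared between NK cells titled as tumour-infiltrating (tuNK, 4 libraries) and NK cells titled as splenic (spNK, 4 libraries). The cells came from BALB/c mice with a subcutaneous tumour of CT26, a mouse colorectal carcinoma line, from which β2-microglobulin had been deleted so that MHC class I does not reach the cell surface. The tissue tag and source name of all 8 samples give the opposite tissue to the title, and groups and directions here follow the title. The labels do not say whether the replicates came from separate mice, so the p-values measure only the spread between these samples.

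The deposited estimated counts summed to 40560781, 53886933, 45709938 and 41629402 in spNK 1 to 4 and to 38745733, 45404059, 42952497 and 42750351 in tuNK 1 to 4. Between 13562 and 14017 genes per library had at least 10 counts. The first principal component held 86.8% of the variance and separated the groups, and the second held 3.2%. Across genes, which are not independent replicates, Pearson's r between libraries was 0.964 to 0.976 within spNK, 0.969 to 0.977 within tuNK and 0.688 to 0.72 between groups.

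The comparison of tuNK with spNK addresses how NK cells inside the tumour differ from those of the spleen. The tuNK libraries held less RNA of genes for NK cell maturation and for exit from tissue, more RNA of granzymes B and C, and high levels of collagen and other mesenchymal genes. S1pr5, a sphingosine 1-phosphate receptor that guides NK cells out of tissue, was 66.8-fold lower (397 ± 85.7 CPM in spNK, 5.94 ± 2.14 in tuNK), and the chemokine gene Ccl5 was 16-fold lower. Gzmb, which encodes the cytotoxic protease granzyme B, was 2.35-fold higher (669 ± 107 against 1572 ± 322 CPM). The collagen gene Col1a2 stood at 1.42 ± 0.759 CPM in spNK and 1861 ± 470 CPM in tuNK. Of 32 genes expressed across leukocytes, 31 were lower in tuNK, with a median log2 fold change of -1.75, or 29.8% of the spNK level.

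The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 9744 of 14006 genes (69.6%), 4983 higher and 4761 lower in tuNK, and 3061 and 2699 of these changed at least 2-fold. Without spNK 3, which held the most B cell, plasma cell and erythroid markers of its group, and tuNK 1, which held the most mesenchymal markers, 9657 genes were called, 4962 higher and 4695 lower. Scaling to the 32 leukocyte genes, chosen after the mesenchymal genes had been seen, moved the median log2 fold change of all genes by 1.7 and gave 10996 higher and 876 lower genes. Of the 4761 lower genes, 876 stayed lower by that scaling, 2513 turned higher and 1372 were not called, while the 4983 higher genes stayed higher. Log2 fold changes after that scaling are called leukocyte-scaled.

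Positions are on GRCm38 and cover the annotated gene. Ncr1 (ENSMUSG00000062524, chromosome 7, 4337724 to 4345164), which encodes the NK receptor NKp46, fell by 2.23 ± 0.14 on the log2 scale (adjusted p = 2.61e-07; leukocyte-scaled -0.53). S1pr5 (ENSMUSG00000045087, chromosome 9, 21242912 to 21248443) fell by 6.06 ± 0.32 (adjusted p = 3.33e-07; leukocyte-scaled -4.35). Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) fell by 4.00 ± 0.20, from 4038 ± 752 to 252 ± 55.6 CPM (adjusted p = 6.7e-08; leukocyte-scaled -2.28). Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260) rose by 1.23 ± 0.16 (adjusted p = 4.94e-05; leukocyte-scaled 2.91). Gzmc (ENSMUSG00000079186, chromosome 14, 56231441 to 56234656) rose by 7.17 ± 0.86 (adjusted p = 1.28e-04; leukocyte-scaled 8.79). Tigit (ENSMUSG00000071552, chromosome 16, 43648867 to 43664146), an inhibitory receptor gene, rose by 1.78 ± 0.11 (adjusted p = 2.04e-07; leukocyte-scaled 3.47). In all of these the 4 tuNK values lay on one side of the 4 spNK values, and each adjusted p is from the edgeR test.

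Markers of other cell types differed strongly between the groups. The list of fibroblast and mesenchymal tumour cell markers summed to 137 ± 29.7 CPM in spNK and 3663 ± 918 CPM in tuNK (n = 4 each), a log2 difference of 4.72, and its most abundant genes in tuNK were Col1a2, Fn1 (621 CPM), Sparc (411 CPM), Col1a1 (277 CPM) and Cald1 (268 CPM). Genes typical of resident fibroblasts and myofibroblasts in the same list stayed low in tuNK, with Dcn at 12.1 CPM, Lum at 1.68 CPM, Tagln at 1.33 CPM and Acta2 at 1.27 CPM. Epithelial tumour cell markers summed to 4.60 ± 4.60 CPM in spNK (1.28 to 11.4 CPM, highest in spNK 3) and 52.6 ± 7.77 CPM in tuNK (log2 difference 3.56), carried by Krt18, Cdh17 and Krt20. Macrophage and monocyte markers rose by 2.44 on the log2 scale, from 426 ± 152 to 2227 ± 200 CPM, but the rise came from Spp1 (2.46 to 1704 CPM), Ctsb and Cd14. In contrast, Lyz2 fell from 96.4 to 2.16 CPM and Csf1r from 2.83 to 0.0836 CPM. Without spNK 3 their spNK means were 47.6 and 0.956 CPM. In tuNK, Lyz2 was at 1.23 CPM without tuNK 3 and Csf1r at 0.0511 CPM without tuNK 1. By the mean over its genes the macrophage and monocyte list was not called (0.30). Spleen red pulp macrophage markers rose by 5.70, from 26.6 ± 12.9 to 1334 ± 177 CPM, through Axl (4.25 to 1177 CPM) and Vcam1, while Slc40a1 fell from 18.1 to 0.134 CPM. Markers of other innate lymphoid cells rose by 1.73, from 59.6 ± 3.61 to 200 ± 22.3 CPM, through Il1rl1, while Gata3 fell, and the mean over the list's genes gave a log2 difference of -0.04.

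Blood cell markers were higher in spNK. B cell markers fell by 4.97 on the log2 scale, from 2129 ± 1331 CPM in spNK to 55.7 ± 7.03 CPM in tuNK, and the plasma cell marker list fell by 2.14 (-2.73 without spNK 1), from 603 ± 401 to 107 ± 15.3 CPM. Erythroid markers changed by -3.32 (954 ± 440 to 90.3 ± 29.5 CPM) and platelet and megakaryocyte markers by -5.97 (450 ± 123 to 6.05 ± 0.847 CPM). The mast cell and basophil list had a log2 difference of -4.75 (343 ± 40.6 to 11.8 ± 1.20 CPM), mostly from Cma1, which is also in the list of mature NK genes. T cell markers had a log2 difference of -1.58 (406 ± 41.6 to 136 ± 21.7 CPM), dendritic cell markers -0.67 (795 ± 178 to 493 ± 59.1 CPM), endothelial markers -0.97 (116 ± 3.80 to 59.6 ± 9.73 CPM) and mitochondrially encoded transcripts -0.52 (37260 ± 2539 to 26390 ± 5698 CPM), and all 4 turned higher when scaled to the leukocyte genes, by 0.26, 1.18, 0.86 and 1.32. The dendritic cell list holds Bst2, also an interferon response gene, which rose from 25.8 to 203 CPM, whereas its class II genes H2-Aa and H2-Ab1 fell. The T cell list holds Tcf7, also in the immature NK list, at 148 CPM in spNK and 39.7 CPM in tuNK. Neutrophil markers were not called by summed CPM (log2 difference -0.28, exact permutation p = 0.629, leukocyte-scaled 1.53). They were called lower by summed TPM (-2.92, adjusted p = 0.033) and by the mean over genes (-0.82, adjusted p = 0.0357). Each of the other 14 of the 15 lists had an exact permutation p of 0.0286, the smallest this design allows, and an adjusted p of 0.0306, with 5 higher and 9 lower in tuNK. Plasma cell markers were not called after leukocyte scaling (-0.30), nor by summed TPM (-1.54), dendritic cell markers were not called by summed TPM (-0.28) and endothelial markers were not called by the mean over genes (-0.44).

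**Figure D1:**
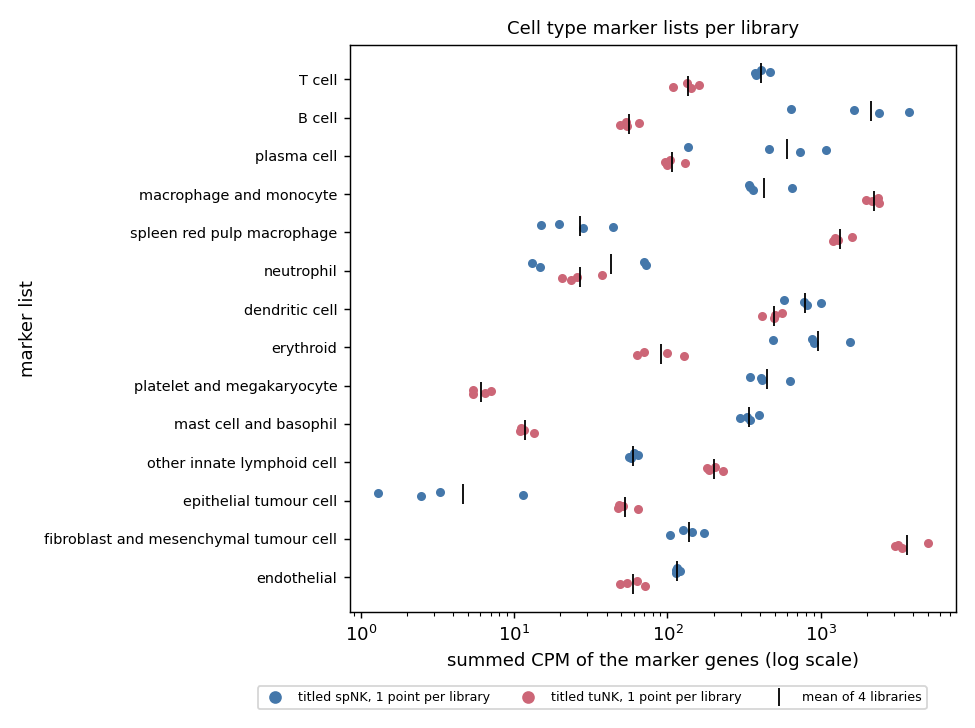
Summed CPM of 14 cell type marker lists (horizontal axis, log scale) in each library, with 1 point per library for spNK and tuNK and a black bar at the mean of 4. The mesenchymal list lies at 137 ± 29.7 CPM in spNK and 3663 ± 918 CPM in tuNK, and the B cell, erythroid and platelet lists are higher in spNK; the T cell, dendritic and endothelial lists, lower in tuNK here, turn higher when scaled to leukocyte genes.

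Each gene list was fixed before the data were examined. Camera called 19 of 27 lists, 10 higher and 9 lower in tuNK, and fry called 25, 15 higher and 10 lower. The 6 lists called by fry alone were tissue residency, TGF-beta response, oxidative phosphorylation, endoplasmic reticulum stress and heat shock (higher) and chemokine receptors (lower). With an estimated correlation between genes, camera called 0 lists, with adjusted p from 0.292 to 0.927, so the p under that setting is given beside each list. After leukocyte scaling camera, which compares a list with other genes, called 18 lists, 9 higher and 9 lower, and fry, which does not, called 26, 22 higher and 4 lower. The 2 tests then went opposite ways, lower by camera and higher by fry, for the cytotoxic granule, inhibitory receptor, immature NK and chemokine receptor lists. Adjusted over the list alone, the counts of changed members were the same as those over all genes for every list except cytokine receptors (17 lower in place of 16), TGF-beta response (8 lower in place of 7), NR4A (9 lower in place of 8) and ribosomal proteins (32 higher in place of 31). The tuNK libraries that give these values also held the mesenchymal RNA described (3663 ± 918 CPM of markers) and the leukocyte genes at 31.4 ± 4.5% of the spNK level (n = 4).

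NK identity genes fell together. Of 19 members 18 were lower and 1 was higher, with a median log2 fold change of -1.96 (leukocyte-scaled -0.25, still lower by fry), a camera adjusted p of 5.66e-12, and adjusted p = 0.292 with an estimated correlation. Eomes and Tbx21, the T-box factors that specify NK cells, changed by -2.51 and -3.15, and the receptor genes Klrb1c (NK1.1 family) and Itga2 (the DX5 antigen) by -2.71 and -3.70, all of which stayed lower after leukocyte scaling. Klrd1, which encodes CD94, fell by 1.59, but its leukocyte-scaled change was 0.11. The member that rose was Nfil3, a factor needed for NK development (1.05, named after its values were seen). Activating receptors and adaptors behaved alike, with 26 of 27 lower, a median of -1.83 (leukocyte-scaled -0.12), a camera adjusted p of 2.46e-12 and adjusted p = 0.292 with an estimated correlation. The signalling genes Cd247 and Lat changed by -2.47 and -2.31. The Ly49 list holds genes of receptors for MHC class I and the pseudogene Klra13-ps. Of its 10 tested members 8 were lower and 1 was higher. The median was -1.77 (leukocyte-scaled -0.06), with a camera adjusted p of 0.0146 and adjusted p = 0.505 with an estimated correlation. Klra3 fell by 1.74 (leukocyte-scaled -0.03) and Klra7 fell by 1.16 but was higher by 0.52 when scaled to leukocyte genes. The fall of these lists stood beside the fall of the 32 leukocyte genes, median -1.75.

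Genes of mature NK cells fell further than the leukocyte genes. Of 16 members 14 were lower and 0 higher, with a median of -2.42 (leukocyte-scaled -0.75), a camera adjusted p of 1.01e-08 and adjusted p = 0.292 with an estimated correlation. Cma1 was 41.5-fold lower (297 ± 63.7 to 7.16 ± 0.956 CPM), Rap1gap2 20.2-fold lower, and Itgam, which encodes CD11b and is also a myeloid gene, 13.5-fold lower (419 ± 88.4 to 31.0 ± 10.8 CPM). Klrg1, a receptor of terminally mature NK cells, fell by 2.37 (leukocyte-scaled -0.68), and Zeb2, a factor of the same stage, fell by 2.30 but was not called after leukocyte scaling (-0.57). Genes of immature NK cells were also lower, 12 of 14 with 2 higher, with a median of -1.76 (leukocyte-scaled -0.06, called higher by fry and lower by camera), a camera adjusted p of 7.4e-04 and adjusted p = 0.292 with an estimated correlation. Il7r, the receptor of interleukin 7, changed by -3.71 and Bach2 by -2.82, both still lower when scaled to leukocyte genes, whereas Cd27 fell by 1.48 and was at 0.20 after that scaling.

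Genes of recirculation and lymphoid homing were lower for 14 of 15 members, with a median of -2.39 (leukocyte-scaled -0.71), a camera adjusted p of 4.02e-09 and adjusted p = 0.292 with an estimated correlation. Besides S1pr5, the sphingosine receptor genes S1pr1 and S1pr4 changed by -3.99 and -3.34, the integrin gene Itga4 by -4.23 (562 ± 65.2 to 29.9 ± 6.15 CPM) and Rasgrp2, an activator of integrin adhesion, by -4.34, and all stayed lower when scaled to leukocyte genes. Klf2, which drives S1pr1, fell by 1.73, but its leukocyte-scaled change was -0.04 and was not called. The member that rose was Cxcr4, by 1.64. Of 16 chemokine receptor genes 9 were lower and 2 higher, with a median of -1.61 (leukocyte-scaled 0.08, called higher by fry and lower by camera, adjusted p = 0.00807), a camera adjusted p of 0.181 and adjusted p = 0.505 with an estimated correlation. Cxcr3, a receptor for inflammatory chemokines, fell by 1.66, but was at 0.03 after leukocyte scaling. Ackr3, a scavenging receptor that mesenchymal cells also express, rose by 8.24 (8.84 without spNK 1) beside the mesenchymal markers.

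Cytotoxic granule genes moved in both directions. Of 23 members 16 were lower and 6 higher; the median was -1.30 and the mean 1.04, the camera test was in the direction of the median (adjusted p = 0.00478, and adjusted p = 0.531 with an estimated correlation), the call was lost with the replicate block (adjusted p = 0.0675), and the leukocyte-scaled median was 0.37. Gzma (granzyme A) fell by 1.56, from 7298 ± 1165 to 2477 ± 473 CPM, and Prf1 (perforin) fell by 1.35, whereas after leukocyte scaling Gzma was at 0.13 and not called and Prf1 was higher by 0.34. Nkg7 and Gzmk changed by -2.19 and -2.24 and stayed lower. Gzmb was higher in all 4 tuNK libraries, and Gzmc stood at 94.0, 149, 213 and 848 CPM in the tuNK libraries against 2.25 ± 0.377 CPM in spNK, a rise of 6.06 without tuNK 4. Gzmd, Gzme and Gzmf, named after their values were seen, had 0 counts in spNK and were at least 920-fold, 416-fold and 304-fold higher in tuNK (245-fold, 117-fold and 68.7-fold without tuNK 4), though reads of these near-identical genes can be exchanged between them. Lamp1, a lysosomal gene of many cell types, rose by 1.14 beside the mesenchymal markers.

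Secreted cytokine and chemokine genes had 7 higher, 6 lower and 5 not called of 18, with a median of -0.20, a mean of 0.85, a leukocyte-scaled median of 1.49, a camera adjusted p of 0.53 and adjusted p = 0.735 with an estimated correlation. Ccl3 fell by 1.74 (leukocyte-scaled -0.02, not called), and Il16 had a change of -2.83. Xcl1, a chemokine that attracts dendritic cells, rose by 0.54 (not called against a fold of 1.5 or on log2 TPM of all genes above 0), and Mif, a cytokine made by many cell types, by 2.24. Ifng had a log2 fold change of -0.28 (adjusted p = 0.317), but without spNK 3 it was called lower (-0.48, adjusted p = 0.0386), and its leukocyte-scaled change was 1.44. Csf2 rose by 1.51 (adjusted p = 0.0177), which rested on tuNK 1, since without it the value was 0.70 and was not called (adjusted p = 0.0767), nor was it called on log2 TPM or against a fold of 1.5. Areg, an epidermal growth factor family member, had 0 counts in spNK and was at least 78.3-fold higher in tuNK.

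**Figure D2:**
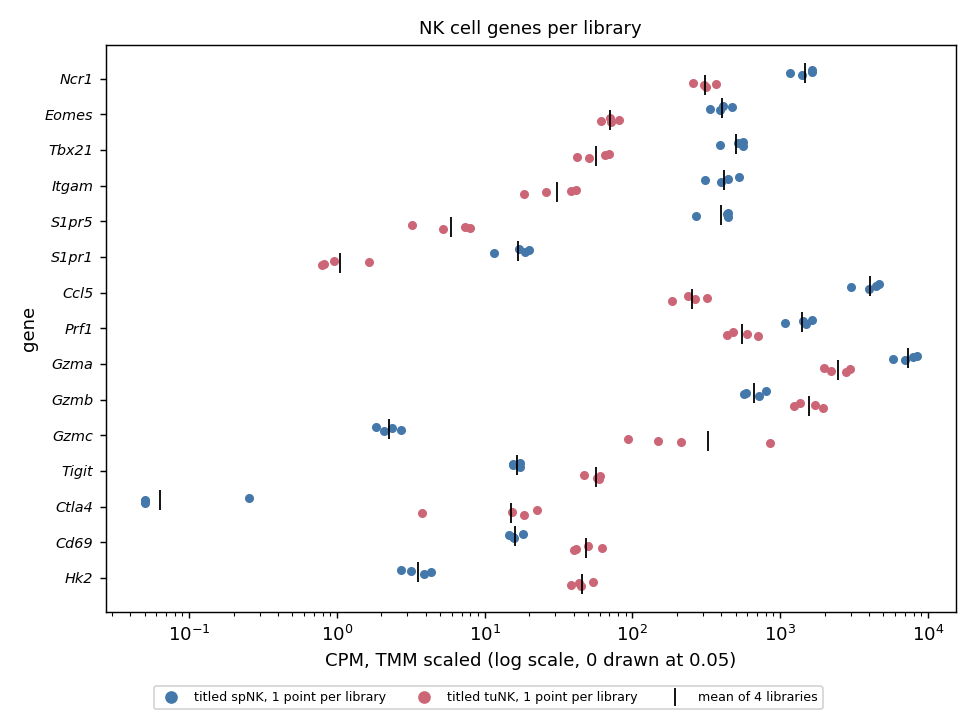
TMM-scaled CPM of 15 NK cell genes (horizontal axis, log scale, 0 drawn at 0.05), with 1 point per library for spNK and tuNK and a black bar at the mean of 4. S1pr5 lies at 397 ± 85.7 CPM in spNK and 5.94 ± 2.14 CPM in tuNK and Gzmb at 669 ± 107 and 1572 ± 322 CPM, while Prf1, lower in tuNK here, turns higher when scaled to leukocyte genes, and Gzma, also lower here, is then not called.

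Inhibitory receptors and checkpoints were lower for 13 of 22 members and higher for 3, with a median of -1.20 (leukocyte-scaled 0.51, higher by fry and lower by camera), a camera adjusted p of 0.0252 and adjusted p = 0.505 with an estimated correlation. On log2 TPM the list was not called (adjusted p = 0.0537). The 3 that rose were Tigit (16.5 ± 1.05 to 56.4 ± 6.10 CPM), Lag3 (11.4 ± 1.62 to 24.4 ± 10.6 CPM) and Ctla4 (0.064 ± 0.128 to 15.0 ± 8.05 CPM), which encode receptors that restrain lymphocytes. Ctla4 had a fitted log2 fold change of 7.93, which rests on the few Ctla4 reads of spNK 1. Without spNK 1, Ctla4 had 0 reads in spNK, so the value then fitted, 12.37, does not measure the size of the rise. Tox, a factor of persistently stimulated lymphocytes, fell by 2.10, and Cd160 fell by 1.48 but was at 0.20 after leukocyte scaling. Pdcd1 (PD-1) and Havcr2 (TIM-3) were near 1 CPM in tuNK and were not called, at 1.11 and -0.10. T cell markers, whose cells share these receptors, summed to 136 ± 21.7 CPM in tuNK.

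Genes of tissue residency and type 1 innate lymphoid cells had 9 higher, 4 lower and 8 not called of 21, with a median of 0.54 (leukocyte-scaled 2.25), a camera adjusted p of 0.181 and adjusted p = 0.627 with an estimated correlation. Cd69, which retains lymphocytes in tissue, rose by 1.59, Tmem176a and Tmem176b by 3.67 and 3.73, and the integrin gene Itgav by 1.51. Itga1, which encodes the residency marker CD49a, rose by 1.08 (adjusted p = 0.0273), but was not called without spNK 2, spNK 3, tuNK 1, tuNK 2 or tuNK 4, with values of 0.94, 0.90, 1.05, 1.09 and 0.84, nor by library size alone (0.92), on log2 TPM or against a fold of 1.5. Itgae (CD103) was at -1.06 and not called (adjusted p = 0.0539), but was called lower without spNK 4 (-1.30) and under 6 other alternatives (upper quartile, library size, CPM filter, DESeq2 and both log2 TPM offsets, adjusted p from 0.0278 to 0.0457). After leukocyte scaling Itgae was at 0.58 and not called. Cxcr6 was at -0.21 and not called, but was called lower on log2 TPM of the tested genes (-0.38) and reached 1.47 after leukocyte scaling. TGF-beta response genes had 9 higher and 7 lower of 22 (8 lower adjusted over the list alone), with a median of -0.02 against a mean of 0.64, a leukocyte-scaled median of 1.69, a camera adjusted p of 0.619 and adjusted p = 0.836 with an estimated correlation. Smurf1, Rgs16 and Tgif1 rose by 2.01, 3.53 and 1.75, Smad3 fell by 1.39 but was at 0.34 after leukocyte scaling, and Smad7 was at 0.01 (leukocyte-scaled 1.72, called). Mesenchymal cells, whose markers rose in tuNK, express integrins and TGF-beta targets as well.

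Cytokine receptor genes had 9 higher and 16 lower of 26 (17 lower adjusted over the list alone), with a median of -0.63 (leukocyte-scaled 1.08), a camera adjusted p of 0.029 and adjusted p = 0.486 with an estimated correlation. The call was lost without spNK 1 (adjusted p = 0.0706), without spNK 3 (adjusted p = 0.0615) and on log2 TPM (adjusted p = 0.144). The interleukin 18 receptor genes Il18r1 and Il18rap changed by -2.40 and -2.25 and stayed lower by leukocyte scaling. Il2rg and Tgfbr2 changed by -1.53 and -0.52 but were at 0.17 and 1.18 by that scaling, and Tgfbr2 was not called against a fold of 1.5. Il2ra, which encodes the high-affinity interleukin 2 receptor chain, rose by 1.82. NR4A and antigen receptor type activation genes had 10 higher and 8 lower of 23 (9 lower adjusted over the list alone), with a median of -0.17, a mean of 0.00, a leukocyte-scaled median of 1.55, a camera adjusted p of 0.837 and adjusted p = 0.927 with an estimated correlation. Tnfrsf9, which encodes the activation receptor 4-1BB, rose by 1.72, Nr4a1 by 2.20, Dusp6 by 4.03 and Dusp4 by 6.69 (7.32 without spNK 3), while Nfatc1 fell by 1.94 and was not called after leukocyte scaling (-0.24). Immediate early genes, which many cell types switch on within minutes of stimulation or tissue digestion, were higher for 16 of 23 members and lower for 0, with a median of 1.87 (leukocyte-scaled 3.59), a camera adjusted p of 0.00638 and adjusted p = 0.699 with an estimated correlation. Fos rose by 6.04 (4.60 ± 0.299 to 303 ± 93.3 CPM), Egr1 by 5.30 and Dusp1 by 5.09.

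Camera called 5 of 6 metabolic lists higher in tuNK, all but oxidative phosphorylation, beside the mesenchymal markers of cells that express such genes too. All 23 targets of ATF4, the factor that answers amino acid shortage, were higher, with a median of 3.28 (leukocyte-scaled 4.99), a camera adjusted p of 3.04e-15 and adjusted p = 0.292 with an estimated correlation. Atf5 rose by 6.07 (8.82 ± 0.504 to 591 ± 92.2 CPM), Psat1, an enzyme of serine synthesis, by 3.28 and Atf4 itself by 2.67. Of 19 glycolysis genes 14 were higher and 4 lower, with a median of 1.46 (leukocyte-scaled 3.18), a camera adjusted p of 9.73e-07 and adjusted p = 0.292 with an estimated correlation. The hexokinase gene Hk2 was 12.8-fold higher, Pgk1 6.48-fold and Pkm 4.57-fold. Cholesterol synthesis genes were higher for 21 of 23 and lower for 2, with a median of 1.44 (leukocyte-scaled 3.16), a camera adjusted p of 9.08e-07 and adjusted p = 0.403 with an estimated correlation. Fdps and Cyp51 rose by 3.67 and 3.60. Hypoxia genes were higher for 15 of 23 and lower for 4, with a median of 1.26 (leukocyte-scaled 2.94), a camera adjusted p of 0.00595 and adjusted p = 0.356 with an estimated correlation. The angiogenic factor gene Vegfa and the lactate exporter gene Slc16a3 rose by 4.87 and 3.44. Targets of NRF2, the factor of the oxidative stress response, were higher for 14 of 20 and lower for 3, with a median of 0.72 (leukocyte-scaled 2.42), a camera adjusted p of 0.00638 and adjusted p = 0.292 with an estimated correlation. Me1 and Slc7a11 rose by 8.59 and 5.85. Oxidative phosphorylation genes were higher for 19 of 33 and lower for 3, with a median of 0.29 (leukocyte-scaled 1.99), a camera adjusted p of 0.234 and adjusted p = 0.832 with an estimated correlation. Atp5c1 rose by 0.86.

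Interferon response, proliferation and ribosomal protein genes were called higher by camera, in the same libraries as the mesenchymal markers. Endoplasmic reticulum stress and heat shock lists were not called by camera but were called higher by fry (adjusted p = 5e-04 and 0.0105). Type I interferon response genes were higher for 19 of 34 and lower for 4, with a median of 1.61 (leukocyte-scaled 3.31), a camera adjusted p of 0.0258 and adjusted p = 0.735 with an estimated correlation. The list was not called without spNK 3 and tuNK 1 together (adjusted p = 0.0742) or by camera after leukocyte scaling (adjusted p = 0.115). Isg15, a ubiquitin-like interferon product, rose by 1.79 and Bst2 (tetherin) by 2.97. Endoplasmic reticulum stress genes were higher for 12 of 22 and lower for 4, with a median of 0.31 (leukocyte-scaled 2.01), a camera adjusted p of 0.181 and adjusted p = 0.699 with an estimated correlation. The chaperone gene Hspa5 rose by 1.16. Heat shock genes were higher for 10 of 16 and lower for 0, with a median of 0.70 (leukocyte-scaled 2.39), a camera adjusted p of 0.234 and adjusted p = 0.743 with an estimated correlation. Hspa1a rose by 3.87 (4.55 without spNK 4). Of 25 genes of the G2 and M phases 24 were higher and 0 lower, with a median of 1.74 (leukocyte-scaled 3.40), a camera adjusted p of 1.84e-05 and adjusted p = 0.505 with an estimated correlation. Anln and Ube2c rose by 4.16 and 2.80. Mki67, the proliferation marker, was at 0.32 and not called (adjusted p = 0.496), but was called higher without spNK 3 (0.79) and after leukocyte scaling (1.96). Of 25 S phase genes 18 were higher and 1 lower, with a median of 0.87 (leukocyte-scaled 2.55), a camera adjusted p of 0.029 and adjusted p = 0.735 with an estimated correlation. The list was not called without spNK 1 (adjusted p = 0.0631) or without spNK 4 (adjusted p = 0.05). Cytosolic ribosomal protein genes were higher for 31 of 37 and lower for 0 (32 higher adjusted over the list alone), with a median of 0.59 (leukocyte-scaled 2.28), a camera adjusted p of 0.00947 and adjusted p = 0.735 with an estimated correlation. Ribosomal proteins took 11.95 ± 0.979% of counts in spNK and 15.8 ± 1.75% in tuNK.

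**Figure D3:**
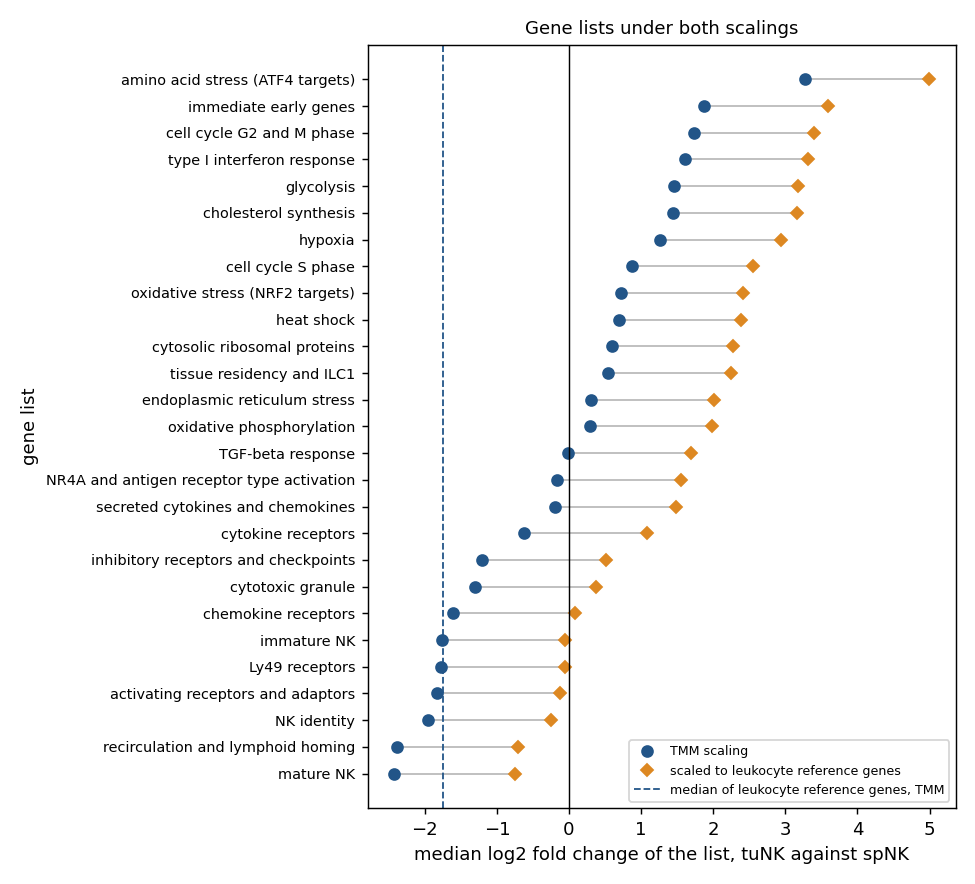
Median log2 fold change, tuNK against spNK, of 27 gene lists (horizontal axis), with a blue circle under TMM scaling, an orange diamond when scaled to 32 leukocyte genes and a dashed line at the TMM median of those genes, -1.75. Mature NK (-2.42 and -0.75) and recirculation genes (-2.39 and -0.71) lie lowest under both scalings, while inhibitory receptors, cytotoxic granule, cytokine and chemokine receptor, secreted cytokine, NR4A and TGF-beta lists change sign.

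The genes with the largest changes lay outside the NK programs. The 10 with the largest rise had 0 counts in spNK: Cyr61 was at least 9160-fold higher (6080-fold without tuNK 1), Msln 3460-fold, Parva 2730-fold, Ddr2 2080-fold, Klk10 1880-fold, Kirrel 1650-fold, Adh7 1320-fold, Prkg2 1230-fold, Col8a1 1200-fold and Ereg 1150-fold. Cyr61 (ENSMUSG00000028195, chromosome 3, 145646976 to 145649981), a matrix-associated signalling protein, stood at 578 ± 430 CPM in tuNK, and its call was lost with limma-voom (adjusted p = 0.0506). Msln, Ddr2 and Col8a1 encode mesothelin, a collagen receptor and a collagen. The 10 with the largest fall had 0 counts in tuNK: Vwf was at least 877-fold lower, Ermap 841-fold, Pklr 638-fold, Mpo 590-fold, Clec1b 449-fold, Tubb1 422-fold, Cldn13 360-fold (228-fold without spNK 3), Pcp4l1 360-fold, Aldh1a1 308-fold and Tspan33 301-fold. Vwf (ENSMUSG00000001930, chromosome 6, 125546774 to 125686679), Clec1b and Tubb1 are genes of platelets and megakaryocytes, Ermap and Pklr of red cell precursors and Mpo of neutrophil precursors, beside the platelet and erythroid markers that were higher in spNK. Counting all genes called, 329 had 0 counts in spNK and 195 had 0 counts in tuNK.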

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

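Of the tests reported in this part, those on the NK identity, mature NK, recirculation, activating receptor and cytotoxic granule genes were chosen only after the result was seen, as were the scaling to leukocyte genes and the use of B2m.

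Among 331 groups of 4 values checked (named genes and marker lists), 29 (8.8%) held a library set apart by more than Dixon's 95% critical ratio, where chance alone gives about 1 in 20. By library these were 11 in spNK 3, 9 in tuNK 1, 4 in tuNK 4, 3 in spNK 4 and 2 in spNK 2. In spNK 3 the ratio was 0.946 for the summed macrophage and monocyte markers (654 CPM against 343 to 360 CPM in the others), 0.916 for Pgk1, 0.887 for Pcna, 0.872 for Prdx1, 0.845 for Tpi1, 0.838 for Chaf1a and 0.834 for Kif20a, each highest in that library. It was 0.94 for S1pr5 (269 CPM against 434 to 444 CPM), 0.923 for Egr1, 0.859 for Nfatc1 and 0.835 for Il16, each lowest there. In tuNK 1 the highest values were those of Tgif1 (ratio 0.92), Vldlr (0.918), Hsp90ab1 (0.916), Col8a1 (0.915), Klf4 (0.841), Csf2 (0.838), Kif20a (0.836), Anln (0.836) and Ddr2 (0.83). In tuNK 4 they were those of Pkm (0.884), Ndrg1 (0.871), Gzmc (0.842, 848 CPM against 94.0 to 213 CPM) and Tnfrsf9 (0.831). In spNK 4 they were those of Vwf (0.875), Hspa5 (0.867) and Smad7 (0.856), and in spNK 2 those of Gzmk (0.83) and Cd27 (0.83).

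Of the 35 splits of the 8 libraries into 4 and 4, only the real split (1 of 35) gave as many genes as the 9744 called, and the highest count of the other splits was 0. The other splits mix libraries of both groups, so the difference between the groups enters their spread and lowers their counts. The count thus goes with the real groups, by a test that can give no share below 1 of 35. The split test does not separate a difference in the NK cells from a difference in other cells, tissue or handling that goes with the groups.

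Mesenchymal markers summed to 3663 ± 918 CPM in tuNK, with Col1a2 at 1861 CPM, and to 137 ± 29.7 CPM in spNK. In spNK, Thy1, also in the immature NK list, stood at 101 CPM. Both groups were sorted by magnetic beads and flow cytometry, which would remove most other cells. A candidate explanation, RNA from non-leukocyte cells in the tuNK libraries, predicts that leukocyte genes fall together, and the median log2 fold change of 32 leukocyte genes, fixed before their values were seen, was -1.75 (31 of 32 lower), as that explanation needs. Low Lyz2 (2.16 CPM), Csf1r (0.0836 CPM), Dcn (12.1 CPM) and Acta2 (1.27 CPM) in tuNK argue against macrophages or myofibroblasts as the main source. Epithelial tumour cell markers, carried by Krt18, Cdh17 and Krt20, were higher in tuNK (52.6 ± 7.77 CPM) than in spNK (4.60 ± 4.60 CPM), which goes with tumour cells as a source. B2m, the gene deleted from the tumour cells, stood at 2027 CPM in spNK and 1936 CPM in tuNK. That tells against tumour cells only if the deletion removed the transcript, which is not given in the sources used here. Neither result excludes other mesenchymal cells, so tumour cells and other mesenchymal cells both stay open. A fall of leukocyte genes or a gain of mesenchymal genes inside the NK cells, as a biological difference between tissues, stays open.

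Genes of NK identity and of mature NK cells were lower in tuNK, and dilution by RNA of non-leukocyte cells was weighed as the whole cause. After scaling to the leukocyte genes the NK identity median was -0.25 (permutation p over genes = 0.27 for a difference of -0.20 from the leukocyte genes), while fry still called the list lower (adjusted p = 6.81e-04). For this list dilution and a fall in the NK cells cannot be told apart, because neither measure decides between them. The difference is within the SD of the median leukocyte level over tuNK libraries (0.21), the range set for dilution alone. That SD is the spread of the leukocyte level between libraries and not the error of the difference, so it cannot decide. The fry call, with 9 members lower and 3 higher, cannot decide either. After that scaling fry called 26 of 27 lists, 22 higher and 4 lower, among them immature NK genes at a median of -0.06. It also takes the scaling as free of error. The mature NK median was -0.75 (difference -0.69, permutation p = 0.0024), with 11 members lower and 4 higher, and fry called the list lower (adjusted p = 4.27e-04). The list thus lay below the leukocyte genes, but the fry call does not exclude dilution as the whole cause, for the reason given for NK identity. The permutation cannot exclude it, since it treats genes as independent while their estimated correlation was 0.485. Of 3 other lists, recirculation genes also lay below the leukocyte genes (difference -0.65, permutation p = 0.0018), but they share S1pr5, Cx3cr1 and Itgb7 with the mature NK list. Activating receptors did not differ detectably by permutation (-0.06, permutation p = 0.54), with Itgb2 and Itgal on both sides of that test. Fry called this list lower after the scaling (adjusted p = 0.0397), with 8 members lower and 5 higher. Cytotoxic granule genes lay above (0.42, permutation p = 0.041). These permutation p-values are not adjusted over the lists. Lower maturity or loss of exit receptors in the tumour may account for a fall beyond that of the leukocyte genes, as may other leukocytes in spNK for members such as Itgam, which was not tested.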

How the results depend on the processing

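Scaling to the leukocyte genes and leaving out spNK 3 with tuNK 1 were chosen only after seeing the data, and the other alternatives before. The count of 9744 genes kept within a factor of 1.5 in each total except a test against a fold of 1.5, which called 6378, 3028 of them lower, because it asks for a larger change. DESeq2 called 10667 genes and kept 99.5% of the calls. Library size alone kept 93.3% and gave 4329 higher and 5510 lower genes, and log2 TPM kept 85 to 88.1% with 1 call turned in each of 3 fits, and gave 3978 to 4062 higher and 5478 to 5546 lower, so lower genes outnumbered higher ones; these settings moved the median log2 fold change of all genes to -0.15 and to between -0.14 and -0.19. Scaled to leukocyte genes, 10996 genes were higher and 876 lower, and 60.1% of the genes called before kept both direction and call. The share of called genes that were higher moved from 51.1 to 92.6%, because that scaling shifts all genes alike. Leaving out 1 library at a time gave 9451 to 9907 genes, 4754 to 5156 higher and 4549 to 4867 lower, and 17 to 19 lists, 9 to 10 higher and 8 to 9 lower. With the replicate number as a block, 9555 genes and 18 lists were called, and the cytotoxic granule list was lost (adjusted p = 0.0675); same-numbered libraries did not deviate together (r from -0.008 to 0.042).

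With an estimated correlation camera called 0 lists, 0 higher and 0 lower, since the estimate widens every list's error. After leukocyte scaling camera called 18 lists, 9 higher and 9 lower: cytokine receptors (adjusted p = 0.215), interferon response (0.115), S phase (0.0619) and immediate early genes (0.0544) lost the call, and chemokine receptors (lower, 0.00807), oxidative phosphorylation (higher, 0.00262) and endoplasmic reticulum stress (higher, 0.00203) gained it. By fry after leukocyte scaling 22 lists were higher and 4 lower, and these medians turned or lost their direction: cytotoxic granule 0.37, secreted cytokines 1.49, inhibitory receptors 0.51, Ly49 -0.06, immature NK -0.06, chemokine receptors 0.08, cytokine receptors 1.08, NR4A 1.55 and TGF-beta response 1.69 (from -0.02). Genes that changed sign with that scaling were Klrd1 0.11, Prf1 0.34, Gzma 0.13, Ifng 1.44, Cd27 0.20, Havcr2 1.53, Itgae 0.58, Cxcr6 1.47, Tgfbr2 1.18, Cd160 0.20, Klra7 0.52, Cxcr3 0.03, Il2rg 0.17 and Smad3 0.34. Marker lists were 9 higher and 4 lower, with mitochondrial transcripts at 1.32, T cell 0.26, dendritic 1.18 and endothelial 0.86. With the mean over a list's genes 3 marker lists were higher and other innate lymphoid cells were at -0.04, the cause of which was not tested. Of 161 named genes, 2070 of 2092 values kept direction and call under the alternatives set beforehand other than leaving out 1 library, 14 lost and 8 gained the call and 0 changed sign; leaving out 1 library, 1279 of 1288 kept both. With 1 library out or with pairs, the smallest exact permutation p of a marker list is 0.0571 or 0.125, so those values say nothing of its call. At this depth genes under the floor of 3 counts cannot be told from 0.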

Other observations

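The scaling to leukocyte genes in this part was chosen only after the result was seen, as were the genes named.

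B2m, H2-K1 and H2-D1 were chosen after their values were seen, and their difference from the leukocyte genes was not tested. B2m, the gene deleted from the tumour cells, was at 2027 ± 285 CPM in spNK and 1936 ± 187 CPM in tuNK (log2 fold change -0.07, edgeR adjusted p = 0.632), and 1.64 after leukocyte scaling. The MHC class I genes H2-K1 and H2-D1 fell by 0.35 and 0.30 (adjusted p = 0.0342 and 0.0461), but rose by 1.37 and 1.41 when scaled to leukocyte genes, and their values in the groups overlapped. The class II genes H2-Aa and H2-Ab1, from the dendritic cell list, fell by 3.13 and changed by -2.43 on the log2 scale, beside the fall of B cell markers. Cd44, an adhesion receptor of activated lymphocytes and of many tumour cells, rose by 1.04, from 191 ± 22.3 to 392 ± 28.8 CPM. Csf1, the macrophage growth factor, rose from 2.91 ± 3.04 (1.43 without spNK 3) to 146 ± 42.7 CPM.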
